A study of Rattus with 6 samples.

How the data were processed

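Small RNA was sequenced from total RNA of rat small intestine, with 3 ASMVT and 3 sham libraries made with the TruSeq Small RNA kit, per the labels' protocols. The rats were male, 6 to 8 weeks old and 300 to 350 g, were fasted for 12 hours before surgery, and the RNA integrity number was above 7.0, per the labels' protocols. The labels speak of 3 tissues in each group and of no pairing, and the time from surgery to sampling is not given in the sources used here. The p-values measure the spread between these libraries.

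Per the file headers, the authors matched the reads to miRBase precursors and mature miRNAs of rat and other species, to the genome and to ESTs, and reported each cluster at the 5' or 3' end of a precursor by its read of highest mapped score. The mapper, its version and the reads removed are not given in the sources used here. The deposited raw columns hold expected counts, which are reads per library and sequence, and the authors divided the reads of a sequence that fits several precursors among those precursors. This was checked on the values: in 83 of 83 pairs of name and sequence listed more than once, the shares were equal within a tolerance of 0.02. Low totals are mostly missing, with 71 of 3515 totals above 0 lying below 4.9, and they look to have been set to 0. The deposited norm columns hold a normalized signal that the authors made by multiplying each raw column by 1 factor, and how they set the factor is not given in the sources used here. The submitters' processing notes name the assembly mRatBN7.2, but deposited coordinates run past the ends of its chromosomes, so the assembly behind them is not settled, and chromosomes are given without coordinates. The table's columns are named control and exp by number, and they were taken as sham and ASMVT with the same replicate numbers.

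Of 941 entries in the table, 522 carry names of rat miRNAs, 346 of other species and 73 are predicted sequences. The rat entries of each mature name, sequence variants included, were summed and rounded to 482 mature miRNAs, so that divided reads were added up to whole reads again. Identical sequences under different names, as for let-7a-5p and let-7c-5p or miR-1-3p and miR-1b, could not be separated. Totals over all entries ran from 1211288 to 7850005 reads. With TMM factors, as used for the levels of rat miRNAs given here, 5 reads stand for 0.60 to 4.03 CPM (reads scaled to library size) by library. Reads without molecular identifiers are not independent molecules, so this limit covers counting error only.

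The groups, the tests, the lists and the alternatives were fixed before the data were examined, except for those named as added later. edgeR 4.0.16 on R 4.3.3 kept 324 miRNAs with filterByExpr (minimum count 10), which hold 99.97% of the rat reads, and scaled them with TMM. Group differences were tested with robust glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjusted p of 0.05 as threshold. The biological coefficient of variation was 0.532 and the prior degrees of freedom 2.91. Of the 19 fixed lists, the 18 with at least 3 measured members were tested with camera from limma 3.58.1, at a preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the lists. DESeq2 gave no adjusted p for 19 of the 324 miRNAs, which its counts leave out. Camera with an estimated correlation and fry were run beside it. The lists are hypoxia, inflammatory, myeloid, lymphocyte, erythroid, epithelial, enterocyte, smooth muscle, endothelial, fibroblast, neuronal, p53, proliferation, let-7, miR-29, miR-30, X-linked (miR-322 and miR-503), Dlk1-Dio3 and other organs. Cell type lists name miRNAs known to be abundant in a cell type, and none is exclusive to it. Arm ratios were tested in limma on log2((5p + 0.5)/(3p + 0.5)), and shares of reads by exact permutation. Other tools were Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

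Named miRNAs had a mean of at least 10 CPM and followed a rule. It took up to 12 called rises and 12 called falls whose groups do not overlap, the 10 smallest p besides if fewer than 10 miRNAs passed, the 5 most abundant, up to 4 members of each list by smallest p, and miR-210-3p. Alternatives were RLE, upper quartile and library total scaling, no filter or a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, a block by replicate number, other thresholds, the most abundant sequence or each entry alone, all entries, and each library left out in turn. Added after seeing the data were the authors' factors, TMM without miR-143-3p, libraries thinned to the depth of the shallowest, DESeq2 with the block or without ASMVT replicate 1, an unadjusted threshold for arm ratios, and library totals for the lists.

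The procedure was tested on simulated data of 324 miRNAs, 60 of them changed, with 3 libraries per group. It recovered 1 of 20 miRNAs changed 2-fold, 8 of 20 changed 4-fold and 16 of 20 changed 8-fold, with 0 false calls at an adjusted p of 0.05. In 20 simulated data sets with no change, 3 had any call. The simulated miRNAs varied independently and no simulated library stood apart, unlike in these data. The rates may therefore not carry over, and they do not cover the list tests.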

Results

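Small RNA from the small intestine of male Sprague Dawley rats was sequenced in 3 libraries of a surgical model that the labels name ASMVT, in which branches of the mesenteric vein were tied off, and in 3 libraries of sham-operated rats, in which the vein was only exposed. The deposited table holds 1211288, 1717366 and 1639460 reads for ASMVT replicates 1, 2 and 3, and 6914127, 7850005 and 1871356 reads for sham replicates 1, 2 and 3. Names of rat miRNAs cover 96.1% to 99.3% of these reads, and 317 to 455 mature rat miRNAs were detected per library. Levels are given as CPM, the reads of a miRNA scaled to library size with TMM factors, as mean ± SD of 3 libraries. Changes are log2 ratios of ASMVT over sham with their standard error (SE). ASMVT replicate 1 stood apart from the other libraries. Across miRNAs, which are not independent replicates, its log2 CPM correlated at 0.867 and 0.911 with ASMVT replicates 2 and 3, against 0.967 between those 2 libraries and 0.959 to 0.966 between sham libraries. The first principal component held 47.3% of the variance, with ASMVT libraries at -21.39, -2.54 and -9.52 and sham libraries at 7.09, 10.88 and 15.48.

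The main comparison asked which miRNAs differ in the intestine after ligation of the mesenteric vein. miR-194-5p and miR-192-5p, which are abundant in intestinal epithelium, were higher in ASMVT. miR-194-5p, encoded on chromosomes 1 and 13, stood at 4153 ± 2271 CPM in ASMVT and 198.9 ± 30.7 CPM in sham (n = 3 each), a 20.9-fold difference. miR-192-5p, encoded on chromosome 1, stood at 2058 ± 996 against 131 ± 13.1 CPM, a 15.7-fold difference. miR-146b-5p, an inducible miRNA that dampens NF-kB signalling, is encoded on chromosome 1 and was 5.08-fold higher, at 4828 ± 1608 against 951 ± 279 CPM. miR-30c-5p, a member of the miR-30 family encoded on chromosomes 5 and 9, was 2.67-fold higher in sham, at 10710 ± 830 CPM against 4005 ± 639 CPM in ASMVT.

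These were the 4 miRNAs of 324 tested that passed an adjusted p of 0.05 in edgeR, 3 up and 1 down. The log2 changes were 4.38 (SE 0.55, adjusted p = 0.0179) for miR-194-5p, 3.97 (SE 0.51, adjusted p = 0.0179) for miR-192-5p, 2.35 (SE 0.39, adjusted p = 0.0428) for miR-146b-5p and -1.42 (SE 0.22, adjusted p = 0.0348) for miR-30c-5p. In each of the 4, all 3 ASMVT libraries lay on the same side of all 3 sham libraries. Of all miRNAs tested, 37 had every ASMVT library above every sham library and 49 had every one below, together 26.5% where chance gives 10% on average. The miRNAs are correlated, so a single split can lie far from 10%, and this difference was not tested. At an unadjusted p under 0.05 there were 63 miRNAs, 28 up and 35 down. In edgeR the count of 4 became 34 without ASMVT replicate 1, 13 without ASMVT replicate 2 (miR-30c-5p then at adjusted p = 0.0529), 0 without ASMVT replicate 3 (43 at an unadjusted p under 0.05), 2 without sham replicate 1 (miR-215 and miR-21-3p), 1 without sham replicate 2 (miR-143-3p) and 0 without sham replicate 3 (50 at an unadjusted p under 0.05). The 4 miRNAs stood at adjusted p of 0.129 to 0.222 without ASMVT replicate 3 and 0.0652 to 0.149 without any 1 of the sham replicates. DESeq2 called 46 miRNAs, 23 up and 23 down, with these 4 among them, and scaling by library total alone called 10, all up, with miR-30c-5p at an adjusted p of 0.118, while miR-146b-5p stood at 0.0563 with RLE factors and 0.0581 with the authors' factors, and miR-30c-5p at 0.0808 with a block by replicate number.

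The 10 miRNAs with the next smallest p did not pass in edgeR, while DESeq2 called all 10 and limma-voom called 2, miR-215 and miR-132-3p (adjusted p = 0.0369 and 0.0422). Of the higher ones, miR-200c-3p, a keeper of the epithelial state, stood at 768 ± 533 CPM in ASMVT and 33.9 ± 17.3 CPM in sham (log2 change 4.49, adjusted p = 0.0656). miR-215, a relative of miR-192, stood at 1754 ± 835 CPM in ASMVT and at 12.0, 0 and 0 CPM in the sham libraries (log2 change 8.62, adjusted p = 0.0795). Its sham level rests on sham replicate 1. Without that library the fitted log2 change was 15.34, which depends on the prior count and is no bound. The table seldom lists totals under 5 reads, so a value of 0 does not show absence. miR-375-3p, abundant in endocrine cells, stood at 377.1 ± 247.5 CPM in ASMVT and at 16.5, 2.60 and 0 CPM in the sham libraries (log2 change 5.77, adjusted p = 0.0888, and 7.67 without sham replicate 1). miR-212-3p and miR-132-3p, which share a precursor cluster and respond to CREB, had log2 changes of 3.24 and 2.40 (adjusted p = 0.0654 and 0.0795). Among the lower ones, let-7g-5p stood at 8849 ± 2314 against 21650 ± 4420 CPM (log2 change -1.29, adjusted p = 0.0795), and miR-148a-3p at 7624 ± 2386 against 20530 ± 6301 CPM (log2 change -1.43, adjusted p = 0.0888). miR-708-3p, miR-499-5p and miR-203b-3p had log2 changes of -2.61, -2.04 and -2.03 (adjusted p = 0.0678, 0.0795 and 0.0888). In edgeR 6 of these 10 passed without ASMVT replicate 1, 6 without ASMVT replicate 2 and 1, miR-215, without sham replicate 1.

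**Figure D1:**
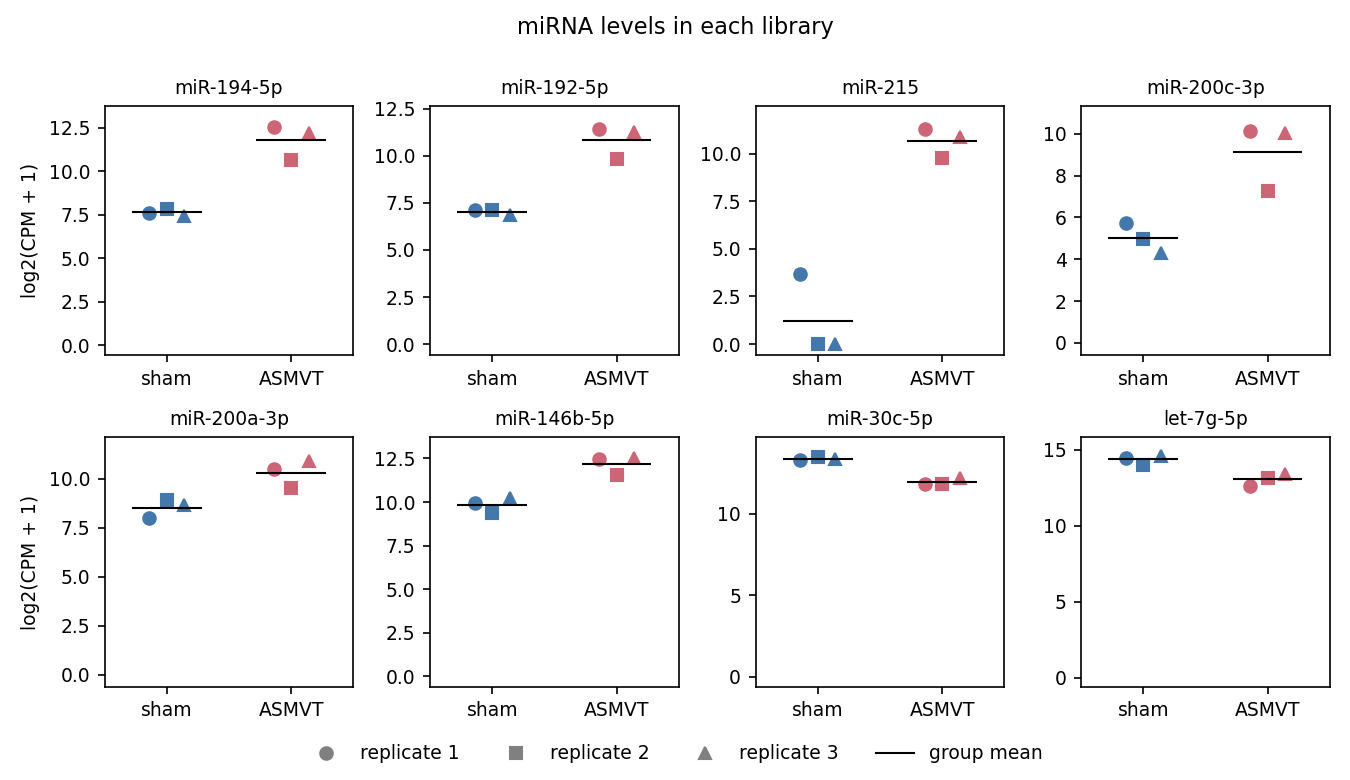
Level of 8 miRNAs in each library, as log2(CPM + 1) on the vertical axis, by group, with a line at the group mean and a symbol per replicate. The ASMVT libraries lie above the sham libraries for the first 6 and below them for miR-30c-5p and let-7g-5p.

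The enterocyte list and the epithelial list ranked above the other miRNAs in ASMVT. All 3 measured members of the enterocyte list, miR-194-5p, miR-192-5p and miR-215, had higher values in ASMVT under each of the 6 scalings. Their median log2 change was 4.38, and 2 rose over all miRNAs tested while 3 rose when adjusted over the list alone. Their summed level was 7965 ± 4090 CPM in ASMVT and 334 ± 43.3 CPM in sham (n = 3 each). Camera gave an adjusted p of 6.99e-05, and an adjusted p of 0.305 with an estimated correlation. The epithelial list, built on the miR-200 family, had positive log2 changes in 10 of its 11 measured members, with a median of 2.08, again under each of the 6 scalings. Its members summed to 5142 ± 2150 CPM in ASMVT and 2266 ± 475 CPM in sham, with ASMVT replicate 2 at 2726 CPM and sham replicate 2 at 2655 CPM. Over all miRNAs tested 0 passed in edgeR, with 7 at an unadjusted p under 0.05, 7 called by DESeq2 and 0 by limma-voom, and 7 rose when adjusted over the list alone. Besides miR-200c-3p and miR-375-3p, miR-200a-3p stood at 1355 ± 592 against 375.9 ± 113 CPM (log2 change 1.85, adjusted p = 0.0919) and miR-429 at 107.3 ± 54.2 against 25.5 ± 7.11 CPM (log2 change 2.08, adjusted p = 0.0918). miR-200a-3p, miR-200c-3p and miR-429 passed without ASMVT replicate 1, each at an adjusted p of 0.0487, and without ASMVT replicate 2, at 0.0276, 0.00234 and 0.0214. Camera gave an adjusted p of 6.99e-05 for the list, and an adjusted p of 0.512 with an estimated correlation. Neither list shares members with another list, and both kept their camera call in all 6 fits that left out 1 library.

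The miR-30 family ranked below the other miRNAs in ASMVT. All 7 measured members had negative log2 changes under each of the 6 scalings, with a median of -0.88, or -0.36 under library totals. Their sum was 57730 ± 6560 CPM in ASMVT and 97910 ± 20100 CPM in sham (n = 3 each). miR-30c-5p fell over all miRNAs tested, and 5 members fell when adjusted over the list alone. miR-30a-5p stood at 22260 ± 990 against 38040 ± 11280 CPM (log2 change -0.77, adjusted p = 0.123), and miR-30a-3p and miR-30e-3p had log2 changes of -1.09 and -0.999 (adjusted p = 0.106 and 0.104). Camera gave an adjusted p of 0.000799, and an adjusted p of 0.295 with an estimated correlation, which was -0.066 for this family. Of the let-7 family, regulators of cell differentiation, 8 of 9 measured members had negative log2 changes, with a median of -0.47, but under library totals alone 4 of 9 were negative and the median was 0.03, where that of all miRNAs was 0.51 instead of 0.08. Over all miRNAs tested 0 passed in edgeR, with 4 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom, and let-7g-5p fell when adjusted over the list alone. let-7f-5p had a log2 change of -0.77 (adjusted p = 0.131), let-7d-5p of -0.69 (adjusted p = 0.123) and let-7a-5p of -0.54 (adjusted p = 0.221). Camera gave the family an adjusted p of 0.0436, and an adjusted p of 0.706 with an estimated correlation. The let-7 call was lost without ASMVT replicate 1, 2 or 3, at adjusted p of 0.138, 0.254 and 0.106, without sham replicate 3, at 0.28, with RLE scaling, at 0.0568, with library totals, at 0.315, with a block by replicate number, at 0.0717, and in fry, at 0.0844.

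The inflammatory list of miRNAs that respond to NF-kB and related signals ranked higher in ASMVT, with positive log2 changes in 9 of 12 measured members (7 of 12 with upper quartile scaling) and a median of 0.96. miR-146b-5p rose over all miRNAs tested, and 5 rose and 1 fell when adjusted over the list alone. The member that fell was miR-9a-5p, also known for its role in neurons (log2 change -1.28, adjusted p = 0.13 over all miRNAs). miR-21-5p, abundant in injured and inflamed tissue, stood at 68540 ± 18750 against 25830 ± 12210 CPM (log2 change 1.41, adjusted p = 0.107). miR-132-3p and miR-212-3p, with the values given among the smallest p, are members of this list. Camera gave an adjusted p of 0.0197, and an adjusted p of 0.706 with an estimated correlation. Without ASMVT replicate 1 the list had an adjusted p of 0.142, while miR-21-5p passed at 0.0487 and miR-9a-5p at 0.0267. Of its measured members, 3 belong to other lists as well.

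The Dlk1-Dio3 list, the miRNAs of a large imprinted cluster, had positive log2 changes in 35 of 38 measured members, with a median of 0.91 and 32 to 36 positive over the 6 scalings. In edgeR 0 of the 38 passed over all miRNAs tested and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 called by limma-voom and 0 by DESeq2, which gave no adjusted p for miR-376c-3p. miR-134-5p, miR-299a-5p, miR-540-3p and miR-495 had log2 changes of 1.61, 1.96, 1.31 and 1.38 (adjusted p = 0.221, 0.264, 0.297 and 0.317). Their levels followed single libraries: the members summed to 1588, 10540 and 6118 CPM in ASMVT replicates 1, 2 and 3, and to 2756, 4186 and 2789 CPM in the sham libraries. Camera gave an adjusted p of 0.0197, and an adjusted p of 0.847 with an estimated correlation. The call was lost without ASMVT replicate 2 or 3, at adjusted p of 0.744 and 0.106, without sham replicate 1 or 3, at 0.14 and 0.092, and with library totals, at 0.212. Without ASMVT replicate 1 camera gave 2.26e-11, and miR-134-5p passed at 0.0207. Together 6 of 18 lists passed in camera, 4 up and 2 down, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. fry, which tests each list on its own, called 2, the enterocyte list (adjusted p = 0.0102) and the miR-30 family (adjusted p = 0.00429).

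**Figure D2:**
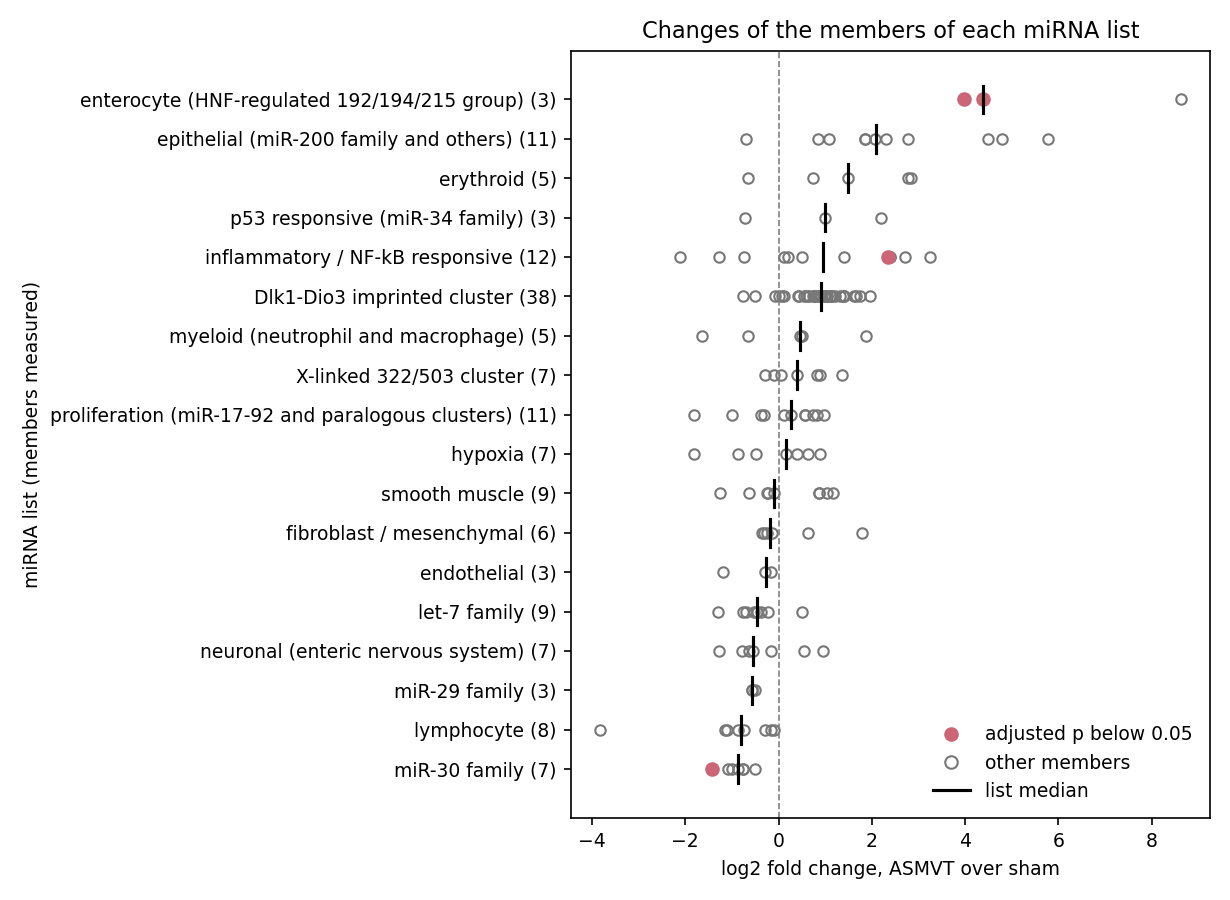
Log2 change of each measured member of the fixed lists on the horizontal axis, a point per miRNA, filled where it passed, and a bar at each list's median. The enterocyte and epithelial lists lie to the right, with medians of 4.38 and 2.08, and the miR-30 family lies to the left at -0.88.

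The other cell type lists did not pass in camera. Of the erythroid list, 4 of 5 measured members had positive log2 changes under each scaling (median 1.49, adjusted p = 0.484), and 0 passed in edgeR over all miRNAs or adjusted over the list alone (1 at an unadjusted p under 0.05, 0 in limma-voom and 0 in DESeq2, which gave no adjusted p for 3 of the 5, miR-451-5p, miR-486 and miR-144-5p). miR-451-5p, the main miRNA of red blood cells, stood at 14362 CPM in ASMVT replicate 1, 1083 and 783 CPM in ASMVT replicates 2 and 3, and 592, 726 and 1040 CPM in the sham libraries. miR-486 stood at 12451 CPM in ASMVT replicate 1 and between 377.1 and 893 CPM in the other libraries. miR-144-5p stood at 359 CPM against 35.2 to 63.4 CPM. The log2 changes of miR-451-5p, miR-486, miR-144-5p and miR-16-5p were 2.78, 2.84, 1.49 and 0.74 (adjusted p = 0.224, 0.266, 0.399 and 0.313), and without ASMVT replicate 1 those of miR-451-5p, miR-486 and miR-144-5p were 0.20, -0.08 and -0.46. Of the myeloid list, 5 members were measured and 0 passed in edgeR over all miRNAs or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 1 called by DESeq2 (median 0.46, adjusted p = 0.488). miR-223-3p, abundant in neutrophils, stood at 830 CPM in ASMVT replicate 1, within a mean of 432 ± 350 CPM, against 118 ± 15.7 CPM in sham (log2 change 1.87, adjusted p = 0.123), and miR-142-3p, miR-146a-5p and miR-511-3p had log2 changes of -1.65, 0.51 and 0.47 (adjusted p = 0.392, 0.464 and 0.604). Without sham replicate 1 the myeloid list passed at the preset correlation (adjusted p = 0.0493) and miR-142-3p had a log2 change of 0.44. Over all libraries camera with an estimated correlation gave the list an adjusted p of 0.792. All 8 measured members of the lymphocyte list had negative log2 changes, but 5 of 8 under library totals alone (median -0.80, adjusted p = 0.199), and 0 passed in edgeR over all miRNAs or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2. miR-150-3p, miR-150-5p, miR-342-3p and miR-181b-5p had log2 changes of -3.82, -1.12, -1.15 and -0.87 (adjusted p = 0.167, 0.399, 0.4 and 0.214). Without sham replicate 3 the lymphocyte list passed at the preset correlation (adjusted p = 0.039), while camera with an estimated correlation gave it 0.792 over all libraries. Without sham replicate 1 miR-150-5p and miR-342-3p had log2 changes of 0.08 and 0.17.

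**Figure D3:**
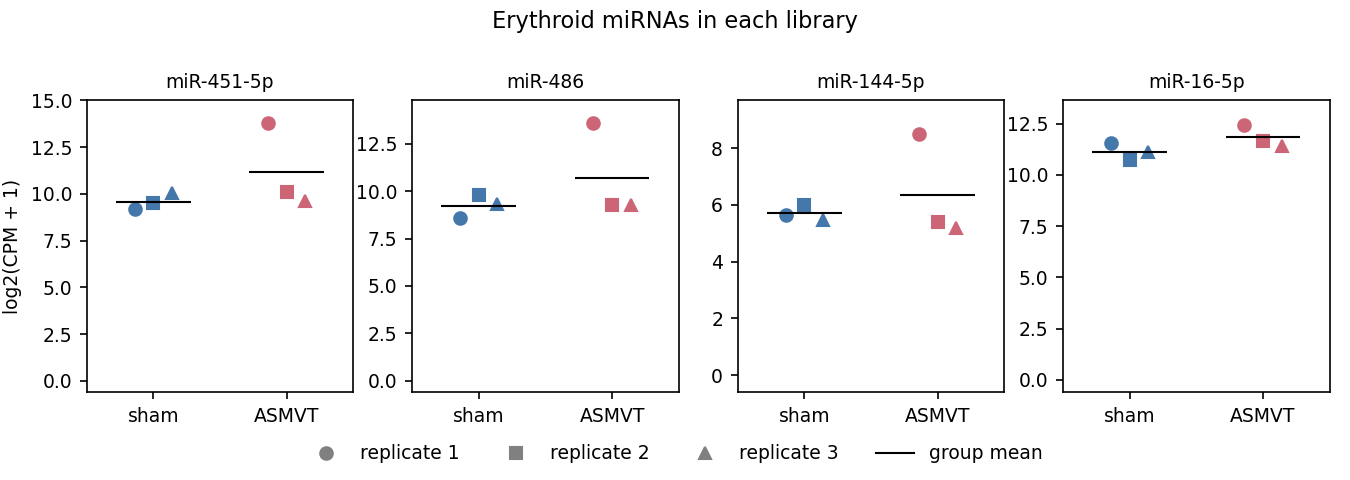
Level of 4 erythroid miRNAs in each library, as log2(CPM + 1) on the vertical axis, by group, with a line at the group mean and a symbol per replicate. ASMVT replicate 1 lies above the other 5 libraries in each panel.

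Of the lists for the wall of the gut and its vessels, none passed in camera, and 0 of their members passed in edgeR over all miRNAs or in limma-voom. At an unadjusted p under 0.05 there was 1 member in each of the smooth muscle, endothelial, fibroblast and neuronal lists, and DESeq2 called 0, 1, 1 and 1. The smooth muscle list had 9 measured members, 4 positive and 5 negative, with a median of -0.09, a mean of 0.16 and a median of 0.41 under library totals (camera up, fry down, adjusted p = 0.968 and 0.977), and 0 passed when adjusted over the list alone. miR-143-3p, the main smooth muscle miRNA, stood at 156800 ± 8478 CPM in ASMVT and 373700 ± 171900 CPM in sham (log2 change -1.25, adjusted p = 0.111, and 0.0155 without sham replicate 2). miR-143-5p had a log2 change of -0.64 (adjusted p = 0.278), and miR-1-3p and miR-1b, which share a sequence, had 0.86 each (adjusted p = 0.313). The endothelial list had 3 measured members with a median of -0.28, or 0.20 under library totals (adjusted p = 0.265), and 1 fell when adjusted over the list alone. That member was miR-126a-5p, at 1097 ± 391 against 2505 ± 214.7 CPM (log2 change -1.19, adjusted p = 0.111), while miR-126a-3p and miR-139-5p had log2 changes of -0.28 and -0.17 (adjusted p = 0.454 and 0.739, with miR-139-5p at 0.06 without ASMVT replicate 2). The fibroblast list had 6 measured members, with a median of -0.19, or 0.27 under library totals, and a mean of 0.23 with camera up (adjusted p = 0.968). Its miR-214-3p rose when adjusted over the list alone, at 2423 ± 1080 against 702 ± 215.2 CPM (log2 change 1.79, adjusted p = 0.0918, and 0.0207 without ASMVT replicate 1). miR-199a-5p, miR-10b-5p and miR-218a-5p had log2 changes of 0.64, -0.32 and -0.35 (adjusted p = 0.558, 0.602 and 0.669, with miR-10b-5p at 0.09 without sham replicate 3). The neuronal list had 7 measured members, with a median of -0.54, or -0.05 under library totals (adjusted p = 0.561), and 0 passed when adjusted over the list alone. miR-138-5p, miR-7a-5p and miR-9a-3p had log2 changes of -0.79, -0.63 and -0.54 (adjusted p = 0.313, 0.598 and 0.602, with miR-7a-5p at 0.26 without sham replicate 1).

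The remaining lists did not pass in camera either, and 0 of their members passed in edgeR over all miRNAs or in limma-voom. At an unadjusted p under 0.05 there was 1 member in each of the hypoxia, p53 and miR-29 lists and 0 in the others, and DESeq2 called 1 in the hypoxia list and gave no adjusted p for miR-34b-3p of the p53 list and miR-122-5p. Except for 1 member of the hypoxia list, 0 passed when adjusted over the list alone. miR-210-3p, the main miRNA induced by hypoxia, stood at 298 ± 71.1 CPM in ASMVT and 266 ± 22.3 CPM in sham (log2 change 0.16, SE 0.31, adjusted p = 0.755, and -0.05 without ASMVT replicate 1). The hypoxia list had 7 measured members, 4 of them in other lists, with a median of 0.16 (-0.15 with upper quartile scaling), a mean of -0.16 and camera down (adjusted p = 0.588). Its miR-103-3p fell when adjusted over the list alone (log2 change -0.87, adjusted p = 0.095, and 0.0487 without ASMVT replicate 1), and miR-107-3p, miR-20b-5p and miR-322-5p had log2 changes of -0.49, -1.82 and 0.88 (adjusted p = 0.397, 0.392 and 0.449, with miR-20b-5p at 0.22 without sham replicate 1). The p53 list had 3 measured members with a median of 0.99 (adjusted p = 0.459), among them miR-34c-5p at 306 ± 86.3 against 154.3 ± 34.4 CPM (log2 change 0.99, adjusted p = 0.166) and miR-34a-5p with a log2 change of -0.72 (adjusted p = 0.266). The proliferation list, from the miR-17-92 cluster and its relatives, had 11 measured members with a median of 0.27 (-0.06 with upper quartile scaling, adjusted p = 0.588), and miR-93-5p, miR-18a-5p and miR-20a-5p had log2 changes of 0.83, 0.97 and 0.57 (adjusted p = 0.392, 0.437 and 0.562). The miR-29 family, which restrains collagen genes, had 3 measured members with a median of -0.58 (adjusted p = 0.199), all negative except for 1 under library totals. miR-29a-3p, miR-29c-3p and miR-29b-3p had log2 changes of -0.58, -0.58 and -0.50 (adjusted p = 0.217, 0.342 and 0.486). The X-linked cluster of miR-322 and miR-503 had 7 measured members with a median of 0.40 (camera up, fry down, adjusted p = 0.968 and 0.977), and miR-322-3p, miR-542-5p and miR-542-3p had log2 changes of 0.40, 1.35 and 0.83 (adjusted p = 0.728, 0.454 and 0.594, with miR-322-3p at -0.29 and miR-542-3p at -0.35 without ASMVT replicate 2). Of the list for other organs only miR-122-5p, the main liver miRNA, was measured, at 1264, 17.2 and 3.10 CPM in ASMVT replicates 1, 2 and 3 and 0.90, 39.5 and 0 CPM in sham (log2 change 4.91, adjusted p = 0.313, and -0.46 without ASMVT replicate 1).

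The composition of the libraries was compared by the shares of the most abundant miRNAs. miR-143-3p led in each library, with 18.4%, 18.7% and 18.7% of rat-named reads in ASMVT and 34.2%, 20.0% and 34.9% in sham. The mean share was 18.6% ± 0.17 in ASMVT and 29.7% ± 8.39 in sham (SD, n = 3 each), a difference of -11.1 points (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). With 1 library left out the difference ran from -15.96 points, without sham replicate 2, to -8.52 points, without sham replicate 3. The 10 most abundant miRNAs took 53.6% ± 2.95 in ASMVT and 60.1% ± 5.63 in sham, a difference of -6.47 points (exact permutation test, p = 0.3), from -9.60 points without sham replicate 2 to -4.16 points without sham replicate 3. Of the other 4 leading miRNAs, miR-26a-5p stood at 49030 ± 7708 against 73200 ± 15330 CPM (log2 change -0.58, adjusted p = 0.217), let-7c-5p, part of whose reads match let-7a-5p equally, at 28850 ± 4172 against 39900 ± 6601 CPM (log2 change -0.47, adjusted p = 0.278) and let-7f-5p at 28990 ± 2360 against 49460 ± 14640 CPM.

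The last comparison asked whether the balance between the 5p and 3p arms of a precursor differed, which library scaling cannot move. miR-374, miR-21, miR-126a, miR-22 and miR-142, chosen after their values were seen, were among the arm pairs with the smallest p. The log2 ratio of 5p over 3p was lower in ASMVT by a difference of -1.36 for miR-21 (adjusted p = 0.366 in limma), -0.97 for miR-126a and -0.86 for miR-22 (adjusted p = 0.351 each), and the difference was 0.97 for miR-142 and 4.31 for miR-374 (adjusted p = 0.351 each). Of 81 pairs tested, 0 passed in limma, and 10 had an unadjusted p under 0.05, 3 with a higher and 7 with a lower ratio in ASMVT. With a pseudocount of 5 counts per arm 1 pair passed, miR-374 with a difference of 2.22 (adjusted p = 0.0417), and without ASMVT replicate 2 there were 2, miR-374 and miR-26b (adjusted p = 0.031 and 0.0395). The 3p arms of these pairs had 0, 12 and 0 reads (miR-374) and 0, 7 and 0 reads (miR-26b) in ASMVT replicates 1, 2 and 3. The size of these ratios rests on the pseudocount and on low totals missing from the table.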

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

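Of the tests in this part, those on the epithelial miRNAs and on the splits of the libraries were chosen after the results were seen. A sequence outside the rat-named miRNAs of the main comparison differed between the groups: cfa-miR-194_R+1, named for the dog and a variant of miR-194 with a longer 3' end. It stood at 1640, 394 and 982 CPM in ASMVT replicates 1, 2 and 3 and at 7.68 ± 1.84 CPM in sham (SD, n = 3), a log2 change of 7.00 (SE 0.70, adjusted p = 0.0157 in edgeR over all entries). Of 125 entries not named for rat that were tested, it was the 1 called, and 29 had an unadjusted p under 0.05, 23 up and 6 down. Some of the 29 have equal values in every library, as those of mmu-miR-3473b and mmu-miR-3473e, and others are length variants, as those of bta-miR-11987. These counts are thus of entries and not of separate results.

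The higher level of the epithelial and enterocyte miRNAs in ASMVT, with a median log2 change of 2.54 over 14 members, was weighed against the sequencing and the make-up of the tissue. The deeper sequencing of 2 sham libraries is argued against by sham replicate 3, with 1871356 reads against 1211288 to 1717366 in ASMVT. Its median log2 CPM was 6.87 for the enterocyte list and 4.26 for the epithelial list. The ASMVT libraries stood at 9.85 to 11.44 and at 6.62 to 8.71. With all libraries thinned to the shallowest the median change was 2.73 over 13 members, but thinning mostly keeps levels on average, so this adds little. A larger share of an epithelium that is the only source of these miRNAs would keep their ratios, and is argued against for part of them: the log2 ratio of the miR-192, miR-194 and miR-215 group to miR-200a, miR-200b and miR-429 was 1.63 ± 0.38 in ASMVT and -0.85 ± 0.55 in sham (SD, n = 3 each), a difference of 2.48, and 7 of the 11 epithelial members had a ratio that was higher in every ASMVT library. It stays open for the other 4, miR-200c-3p, miR-141-3p, miR-375-3p and miR-31a-5p, whose ratios differed by less than the larger group SD. The ratio to miR-200c and miR-141 was 3.59 ± 0.70 against 3.40 ± 0.66, a difference of 0.20. A joint change of level per epithelial cell may give this as well. The difference was -2.22 for miR-375-3p and 1.56 for miR-31a-5p, where the larger SDs were 2.4 and 2.08. Such spreads do not show that these ratios were kept. Sham values of 0 also make the single ratios to miR-141-3p and miR-375-3p depend on the pseudocount. A larger share of epithelium on top of another source of the miR-200 family cannot be told apart from a changed level per cell, since both may leave ASMVT replicate 2 lowest of its group in most members (13 of 14, all but miR-31a-5p), and an effect of the ligation itself and the region of intestine sampled stay open and untested.

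The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For the miRNAs called by edgeR, 1 split, the real one with 4, gave as many, and the highest other gave 0 (46 and 2 in DESeq2). For the lists passing in camera, 2 of 10 splits gave as many as the real 6, and the highest other also gave 6, setting ASMVT replicate 1 with sham replicates 1 and 2. For the arm ratios in limma the real split gave 0, and the highest other gave 1. All 10 splits reach the real count because no count lies below 0, so this comparison cannot decide anything.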

How the results depend on the processing

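Chosen after seeing the data were the authors' factors, TMM without miR-143-3p, thinning, DESeq2 with the block or without ASMVT replicate 1, unadjusted arm ratios and library totals for lists. The count of 4 called miRNAs was 10 with library totals, 7 with no filter, 46 with DESeq2, 22 at an adjusted p under 0.1, 63 at an unadjusted p under 0.05, 31 with DESeq2 and a replicate block, and 73 with DESeq2 without ASMVT replicate 1. With each entry tested alone 7 entries were called, among them 2 of miR-194-5p and 2 of miR-30c-5p. The count of called miRNAs ran from 0 to 34 with 1 library left out (edgeR, 43 and 50 at an unadjusted p under 0.05 where it was 0), and stayed from 3 to 6 under the other settings. The replicate block gave 5 miRNAs, all up, 5 lists without let-7, and 0 arm pairs. miR-30c-5p no longer passed with it (adjusted p = 0.0808, range 6.44e-09 to 0.222 over its alternatives). The labels name no pairing. Deviations of same-numbered libraries correlated at 0.146, 0.14 and -0.08, and those of ASMVT and sham libraries with different numbers at -0.233 to 0.09. With 3 libraries per group, these values cannot decide whether the numbers pair the samples. Of the lists 6 passed, 0 with an estimated correlation and 2 in fry, and 4 to 6 under the other settings. The 0 arm pairs of limma became 1 with a pseudocount of 5, 10 at an unadjusted p under 0.05 and from 0 to 2 with 1 library left out. With 1 library left out the differences in share ran from -15.96 to -8.52 points for miR-143-3p and -9.60 to -4.16 points for the 10 most abundant. The larger group SDs were 8.39 and 5.63. Leaving out 1 of 3 libraries can never move a group mean by as much as its SD, so such moves do not show stability. Over 1015 comparisons of 73 named miRNAs with alternatives, 917 kept direction and side of the threshold, 58 passed newly, 21 no longer passed and 19 changed sign. The 21 losses all fell on the 4 called miRNAs, since only these could lose a call. For the other named miRNAs, passing neither in the main fit nor in the alternative counts as kept. With library totals, which moved the median of all miRNAs from 0.08 to 0.51 where upper quartile scaling moved it to -0.21, the log2 changes were 0.03 for let-7c-5p, 0.20 for miR-126a-3p, 0.29 for miR-139-5p, 0.23 for miR-10b-5p, 0.08 for miR-218a-5p and 0.04 for miR-29b-3p, all below that median. With 1 library left out, log2 changes ran from -2.30 to 0.22 for miR-20b-5p, -2.14 to 0.44 for miR-142-3p, -1.50 to 0.08 for miR-150-5p, -1.56 to 0.17 for miR-342-3p, -0.98 to 0.26 for miR-7a-5p, -0.08 to 3.53 for miR-486, -0.46 to 2.11 for miR-144-5p, -0.46 to 9.26 for miR-122-5p, -0.05 to 0.41 for miR-210-3p, -0.27 to 0.06 for miR-139-5p, -0.51 to 0.09 for miR-10b-5p, -0.35 to 1.29 for miR-542-3p and -0.29 to 0.83 for miR-322-3p. Some that kept their sign also moved with 1 library left out. They ran from 0.03 to 1.25 for miR-322-5p, 0.12 to 1.92 for miR-542-5p, 0.09 to 1.04 for miR-199a-5p and -0.72 to -0.02 for miR-218a-5p. The proliferation members ran from 0.12 to 1.25 for miR-93-5p, 0.52 to 1.56 for miR-18a-5p and 0.19 to 1.04 for miR-20a-5p. Beyond fewer libraries or other scaling by construction, the cause of these moves was not tested. Depth limits miRNAs near 5 reads, which stand for 0.60 CPM in sham replicate 2 and up to 4.03 CPM in sham replicate 3.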

Other observations

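Of the tests in this part, all but that of the low depth of ASMVT replicate 1 were chosen after the result was seen, and the miRNAs of this paragraph were chosen after their values were seen. The miR-200 family members outside the named set had positive log2 changes as well, 2.31 for miR-200b-3p and 4.79 for miR-141-3p (adjusted p = 0.107 and 0.122 in edgeR), while miR-203a-3p, typical of squamous epithelium, had -0.71 (adjusted p = 0.313). miR-141-3p stood at 2.5, 0 and 0 CPM in the sham libraries, so the size of its change rests on sham replicate 1 and on low totals missing from the table. miR-31a-5p, known to rise in inflamed gut epithelium, stood at 372 ± 243 CPM in ASMVT and 53.8 ± 37.9 CPM in sham (log2 change 2.78, adjusted p = 0.122). miR-206-3p, a skeletal muscle miRNA, stood at 114.1, 27.1 and 18.4 CPM in ASMVT replicates 1, 2 and 3, the highest in the library that stands apart, against 7.85 ± 5.17 CPM in sham (log2 change 2.83, adjusted p = 0.123). The entry cgr-miR-215-3p, named for the hamster, stood at 103.3, 23.4 and 55.5 CPM in ASMVT and is listed at 0 in each sham library (adjusted p = 0.0551 in edgeR over all entries).

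The erythroid miRNAs were high in ASMVT replicate 1, with miR-3473 also at 436 CPM there and at 6.50 to 16.2 CPM in the other libraries. The low depth of that library is argued against, because with all libraries thinned to the shallowest its median log2 excess over the erythroid members was 2.99. In the full libraries the median excess was 3.06, and 4 of 5 members were highest there, with miR-486 at 4.35, miR-16-5p at 1.02 and miR-144-3p, the exception, at 0.68. More blood in that piece of tissue stays open, since this excess is the pattern itself and does not test its source. The congestion of the model also stays open and untested, and ASMVT replicates 2 and 3 did not show the excess.

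The miRNAs of the Dlk1-Dio3 cluster differed between libraries of the same group. They may follow the fibroblast miRNAs of each library, since the medians of both lists correlated over the 6 libraries at a Pearson r of 0.86 (exact permutation p = 0.0278, adjusted p = 0.25 over 9 lists) and a Spearman rho of 0.77 (exact permutation p = 0.1028, adjusted p = 0.895). Without ASMVT replicates 1 and 2, the libraries farthest from the median, r was 0.19, so the relation rests on those libraries. Within a group there are 3 libraries, too few to test, and the median log2 CPM of the cluster and of the fibroblast list ran in the same order in ASMVT (3.81, 5.98 and 5.46 against 11.26, 13.39 and 12.69) and in opposite orders in sham (4.64, 5.16 and 4.31 against 12.43, 12.34 and 12.57). Other lists ran with the cluster in both groups. In ASMVT and sham, r was 1 and 0.9 for the endothelial list and 0.94 and 1 for the neuronal list. Over all 6 libraries their r was 0.22 and 0.26. The smooth muscle list ran against the cluster in both groups, at -1 and -0.99. A common source of the cluster and the fibroblast list cannot be told apart from chance with 6 libraries, and a change of the cluster by the ligation stays open and untested.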
